A study of Homo sapiens with 39 samples.

How the data were processed

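The samples are 39 RNA sequencing libraries of RPE1 and CHP-134 cells, in 9 groups taken from the labels. Per the submitters' processing notes the authors used STAR and DESeq2, with no versions named. The genome build, the annotation, the strand setting and the counting rule are not given in the sources used here, so overlapping and antisense genes may share reads. The authors deposited 5 tables, 1 per comparison, and no value per library was analysed here.

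Per the file headers, each of the authors' deposited tables gives for 23710 gene symbols a Status, a mean count, the log2 fold change with its standard error (SE), and a q value, which is an adjusted p-value. The scaling of the mean count is not stated. Values carry 3 significant digits, and a q printed as 0 lies below the smallest value the file could hold. The Status takes 3 levels. Genes with the Status Low had a mean count of at most 10 and a q of 1, and genes with the Status Outlier had a q of 1 at any mean count. The rest are called usable or measured genes. The deposited q values were checked by taking a two-sided normal p-value of the log2 fold change over its SE and adjusting it over usable genes with the Benjamini-Hochberg method. This called 6959 genes against 6963 as deposited in the RPE1 knockout, 2391 against 2388 in CHP-134 clone 1, 5900 against 5898 in clone 2, 236 against 237 in TetOn clone 4 and 362 against 362 in TetOn clone 5.

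The plan, the gene lists and the rule for named genes were fixed before the data were examined. The plan allowed for counts, for normalised values or for the authors' comparison alone. Since the files hold the last, the main result is the authors' q under 0.05 as deposited, and no count model was fitted. The direction of each table is not in its header and was set by the sign of TRIM37. Depth per library is unknown, so no interval or floor that needs it is given. The precision is that of the authors' SE, whose median over usable genes was 0.0551 in the knockout, 0.0863 and 0.0887 in the CHP-134 clones and 0.067 and 0.0653 in the TetOn clones.

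Each of 28 gene lists with at least 5 usable members, a minimum chosen after the data were seen, was tested with cameraPR of limma 3.58.1 in R 4.3.3. The statistic was the log2 fold change over its SE, with a preset correlation of 0.01, TRIM37 left out and Benjamini-Hochberg adjustment over 132 tests. The adjusted p beside a list is from this test. Counts of members up and down are at the authors' q, and the count adjusted over the list alone is given where it differs. A correlation could not be estimated without values per library. The list of mitochondrially encoded genes had 0 usable members.

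Overlaps of called genes were set beside the product of the list sizes over the number of genes usable in both tables, per direction. For the CHP-134 clones, which share their wild type libraries, 100 draws of unchanged groups against common controls were made. The difference between the clones of a pair was tested per gene as the difference of the log2 fold changes over the root of the summed squared SEs, with Benjamini-Hochberg adjustment, which is conservative for the CHP-134 pair. List differences were tested with cameraPR on that statistic over 104 tests, a step added after the data were seen.

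The named genes are, for the knockout and for each pair of clones, the 10 largest rises and 10 largest falls among called genes with a mean count of at least 50. In a pair they were called in both clones with the same sign and ranked by the smaller change. Added to these are TRIM37, 9 further genes fixed in advance, and the 4 members with the smallest q of each list that passed or had at least 3 members called. That last part was first computed over both clones of a pair and then, after its values were seen, per comparison, which is the more literal reading of the rule. Only part of these list members are printed, and 1 of the genes fixed in advance is not reported here. Genes named only because of a count shared across comparisons, and genes said to be so in the closing section, were chosen after their values were seen.

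Chromosomes and gene order came from NCBI RefSeq on assembly GRCh38.p14 by gene symbol, which matched 22699 of the symbols. As the authors' build is not given, no coordinates are printed. Chromosome medians were taken over usable genes with a mean count of at least 100. GC content was that of the longest GENCODE v29 transcript of each symbol, known for 92.2 to 92.6% of usable genes, and its trend was removed by subtracting the median of each of 20 bins.

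Alternatives fixed in advance were other thresholds, minimum fold changes, mean count filters and a null rescaled to the central spread of the statistics, and for lists another preset correlation, ranks and a filtered background. Keeping genes with the Status Outlier, removing the GC trend or the chromosome medians, and leaving out chromosome 12 or a chromosome 3 segment were added after the data were seen. The steps were tested on simulated data. For CHP-134 clone 2 against clone 1, over 12579 genes, 88% of genes changed by 1 on the log2 scale and 70% of those changed by 0.5 were recovered, below the 90% at 1 first set as the bound, which was then relaxed to 80%. For TetOn clone 5 against clone 4, over 11778 genes, these shares were 96% and 69%, with 9 unchanged genes called. The list test, simulated on 12790 genes of CHP-134 clone 1, recovered a p53 list shifted by 1 unit in 96% of 100 draws. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.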

Results

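RNA sequencing measured the transcripts of 2 human cell lines in which the dose of TRIM37, a RING-type ubiquitin ligase, was lowered or raised. RPE1 is an immortalised retinal pigment epithelial line, and CHP-134 is a neuroblastoma line. The 39 libraries comprised 9 of RPE1 wild type, 9 of an RPE1 TRIM37 knockout, 3 of CHP-134 wild type and 3 of each of 2 CHP-134 TRIM37 mutant clones, called clone 1 and clone 2. The rest were 3 untreated and 3 doxycycline-treated libraries of each of 2 RPE1 clones with a doxycycline-inducible TRIM37, called TetOn clone 4 and TetOn clone 5, treated at 1 µM for 24 h. The files used here hold the authors' comparison of each altered group with its control, as a table of 23710 genes per comparison. They hold no value per library, so the depth of each library is unknown and no spread between libraries is given. All fold changes, standard errors (SE) and q values of genes below are the authors', and a gene was called at a q under 0.05. The RPE1 wild type libraries are labelled as 3 sets of 3 and the knockout libraries as 1 to 9. No source used here says what a set is or that the replicates were separate cultures, so these q values may measure technical spread only.

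TRIM37 itself is given first. In the authors' deposited tables its log2 fold change was -1.95, SE 0.0461 in the RPE1 knockout, -1.66, SE 0.0337 in CHP-134 clone 1 and -1.75, SE 0.0416 in CHP-134 clone 2. Doxycycline gave 3.19, SE 0.0441 in TetOn clone 4 and 2.64, SE 0.0419 in TetOn clone 5 in the authors' deposited tables, and all 5 q values were printed as 0. The file headers do not name the numerator, and the direction of each table was taken from TRIM37, so this gene cannot show whether a pair of groups was swapped.

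The RPE1 knockout was compared with its wild type to ask which transcripts differ when TRIM37 is lost. The HOX genes above the count limit, which encode body-patterning transcription factors, rose, and so did targets of the tumour suppressor p53. Targets of the transcription regulators YAP and TEAD fell, and so did NF-kB and inflammatory genes. Of 13002 usable genes, 6963 were called, 3460 up and 3503 down, and of these 359 rose and 421 fell by at least 1 on the log2 scale. In the authors' deposited table the largest rises were of GPR98 (6.10, SE 0.327), the sialyltransferase gene ST8SIA5 (5.71, SE 0.306), TRIML2 (5.67, SE 0.30), the cystatin gene CST1 (5.61, SE 0.279) and HOXB9 (5.46, SE 0.201). KIAA0040, the interferon-induced GTPase gene GBP4, the selenoprotein P gene SEPP1, SESN3 and the transcription factor gene GATA3 followed in the authors' deposited table at 5.40, 5.30, 5.13, 4.70 and 4.53. The largest falls in the authors' deposited table were of the chemokine gene CCL2 (-6.73, SE 0.274), EPDR1 (-6.52, SE 0.278), the heparan sulfatase gene SULF1 (-6.44, SE 0.245), the protease gene CTSZ (-6.00, SE 0.137) and ZNF542 (-5.99, SE 0.31). APBB1IP, IQCA1, CRISPLD2, the adhesion molecule gene CADM1 and the calcium channel gene CACNA1C followed in the authors' deposited table at -5.76, -5.61, -5.33, -5.00 and -4.92. CCL2 had a mean count of 454 in this comparison, but of 0 and 0.393 in those of TetOn clones 4 and 5. Between these 2 clones EPDR1 (319 and 2.17) and CST1 (67 and 0.669) also stood apart, CTSZ (820 and 2810) less so. Some of these genes thus vary between RPE1 lines without loss of TRIM37. The labels name no clone for the knockout, so differences between lines cannot be told apart from effects of TRIM37 loss.

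All 9 measured HOX genes rose in the knockout, with a median log2 fold change of 3.36 (adjusted p = 2.13e-06), and 30 others stayed below the count limit. In TetOn clone 4 only 4 of 39 members were measured, and in clone 5, 0 of 39. A gene near silent in wild type cells reaches the limit only by being high in the knockout. The limit may thus have fixed much of this outcome, and the test is no separate evidence that the list rose. HOXB6 (3.86, SE 0.197), HOXC8 (3.36, SE 0.239) and HOXB3 (3.07, SE 0.146) stood beside HOXB9 in the authors' deposited table. The p53 targets went 27 up and 0 down of 30 (median 0.39, adjusted p = 3.64e-06). MDM2, which encodes the ligase that degrades p53, rose by 0.95, SE 0.037, the cell cycle inhibitor gene CDKN1A by 0.41, SE 0.0275 and the receptor gene EDA2R by 0.73, SE 0.0559 in the authors' deposited table. MDM2 is 1 of 3 p53 targets on chromosome 12, whose genes were higher as a block in this comparison, and 24 of the 27 measured targets on other chromosomes rose as well.

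YAP and TEAD targets fell, 3 up and 18 down of 23 (median -0.30, adjusted p = 1.2e-15). ANKRD1 (-1.04, SE 0.0218), the growth factor gene TGFB2 (-1.20, SE 0.0279), CRIM1 (-0.86, SE 0.0231) and the tissue factor gene F3 (-0.72, SE 0.0176) were among them in the authors' deposited table. NF-kB and inflammatory genes went 4 up and 18 down of 22 (median -0.72, adjusted p = 0.00275). IL11 was at -1.59, SE 0.0601, TNFAIP2 at -1.33, SE 0.0471 and, against the group, the cytokine gene IL1B at 2.06, SE 0.0759 in the authors' deposited table. Extracellular matrix genes split, 11 up and 14 down of 27, with a downward list test (adjusted p = 1.98e-09) that did not pass on ranks (adjusted p = 0.382). The Status Outlier set aside 7 of 34 members above the count limit, and the test passed with these kept (adjusted p = 2.08e-08). The collagen genes COL4A1 (-1.80, SE 0.0272) and COL8A1 (-1.29, SE 0.0187) fell and the laminin gene LAMA4 (1.58, SE 0.027) rose in the authors' deposited table. Schwann cell and fibroblast markers split too, 4 up and 4 down of 11, with a downward list test (adjusted p = 0.00489) that did not pass on ranks (adjusted p = 0.721). The contractile genes TAGLN and ACTA2 were at -1.75 and -0.87 in the authors' deposited table.

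Mesenchymal neuroblastoma genes rose in the knockout, 17 up and 4 down of 26 (adjusted p = 0.000745), among them the caveolin gene CAV1 (0.57, SE 0.016), CD44 (0.36, SE 0.0145) and ANXA1 (0.42, SE 0.0244) in the authors' deposited table. Immediate early genes went 14 up and 7 down of 26, or 15 up and 7 down adjusted over the list alone (adjusted p = 0.000783, and adjusted p = 0.144 on ranks). PHLDA1 was at 1.80, SE 0.0231, the phosphatase gene DUSP6 at 1.33, SE 0.0595 and DUSP1 at -0.89, SE 0.0435 in the authors' deposited table. Cytosolic ribosomal protein genes went 23 up and 2 down of 39, or 25 up and 2 down adjusted over the list alone, with an upward test (adjusted p = 0.00407) that did not pass with a preset correlation of 0.05 (adjusted p = 0.0849). The median of the list was 0.11. RPL6 at 0.74, SE 0.0169 and RPLP0 at 0.50, SE 0.0323 in the authors' deposited table lie on chromosome 12, and the test passed with each chromosome's median removed (adjusted p = 0.00554). Integrated stress and amino acid response genes went 10 up and 16 down of 32, with a downward test (adjusted p = 0.0155) that did not pass with a preset correlation of 0.05 (adjusted p = 0.139) or on ranks (adjusted p = 0.194). The asparagine synthetase gene ASNS was at -0.83, SE 0.0349 and the amino acid transporter gene SLC7A5 at -0.62, SE 0.0271 in the authors' deposited table.

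Centriole and centrosome assembly genes did not pass as a list in the knockout, 4 up and 10 down of 36 (adjusted p = 0.857). Neither did S phase and E2F genes, 7 up and 7 down of 35, or 6 up and 7 down adjusted over the list alone (adjusted p = 0.971), G2 and mitosis genes, 12 up and 7 down of 30 (adjusted p = 0.815), or peroxisome genes, 5 up and 10 down of 31 (adjusted p = 0.804). In the authors' deposited table the centriole duplication kinase gene PLK4 was at 0.077, SE 0.0326, q = 0.0344, the centrosome scaffold gene CEP192 at 0.026, SE 0.0369, q = 0.574 and TP53BP1 at -0.043, SE 0.0293, q = 0.208. The deubiquitinase gene USP28 was at -0.25, SE 0.0526, q = 5.5e-06 and the peroxisomal import receptor gene PEX5, on chromosome 12, at 0.37, SE 0.0369, q = 2.14e-22 in the authors' deposited table. MYCN lay below the count limit.

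**Figure D1:**
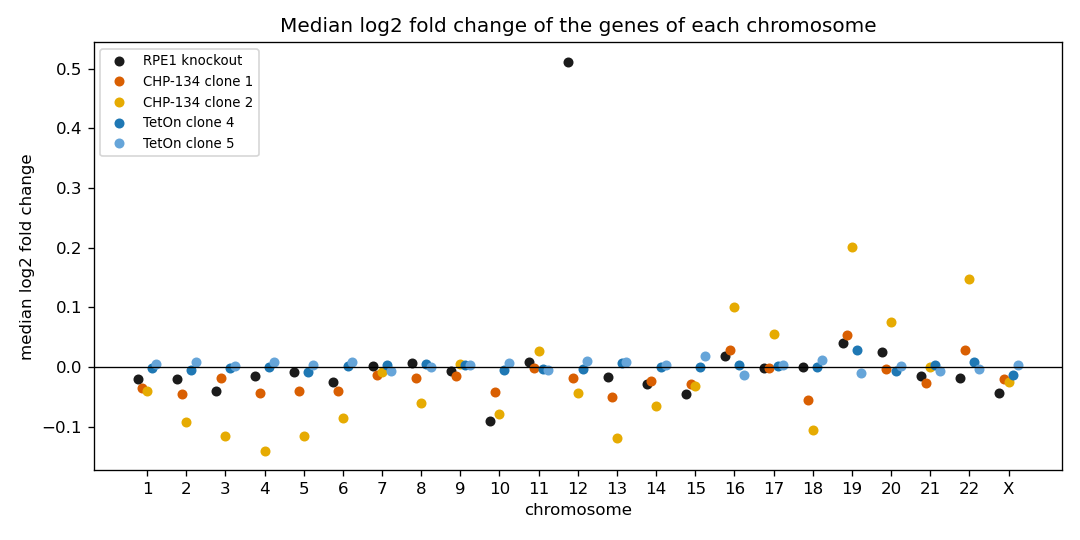
Median log2 fold change (vertical axis) of the genes of each chromosome (horizontal axis), over genes with a mean count of at least 100, with 1 point per comparison. Chromosome 12 of the RPE1 knockout stands at 0.51 and the next highest point, chromosome 19 of CHP-134 clone 2, at 0.20.

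Genes on chromosome 12 were higher in the knockout than genes elsewhere. Of 590 such genes with a mean count of at least 100, 538 were called up and 26 down. Their median log2 fold change was 0.51, against -0.013 for the genes of all other chromosomes. Without chromosome 12 genes 6311 genes were called, 2866 up and 3445 down. The number of calls also rests on the assumed null, as 1262 genes passed once the statistics were rescaled to their own central spread.

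The 2 CHP-134 mutant clones were each compared with the same wild type libraries to ask what lower TRIM37 goes with in a neuroblastoma line. In both clones p53 targets rose and S phase genes fell. Mitosis genes fell too, in clone 2 with a call that ended under some settings. In clone 1, 2388 of 12791 usable genes were called, 1228 up and 1160 down. In clone 2, 5898 of 12771 were called, 2811 up and 3087 down. These numbers rest on the assumed null as well, as 243 genes, 155 up and 88 down, passed in clone 1 and 256, 98 up and 158 down, in clone 2 with the statistics rescaled to their own central spread. With a change of at least 1.5-fold, 321 up and 153 down were called in clone 1 and 878 up and 630 down in clone 2, an upward majority in both. At an absolute log2 fold change of at least 1 that majority was lost in clone 1, with 68 up and 74 down. In clone 2 it was 272 up and 248 down. Among genes called in both clones with the same sign, the largest rises in the authors' deposited tables, given for clone 1 and clone 2, were of EDA2R (1.91 (SE 0.205) and 2.98 (SE 0.19)), the neuronal gene ARC (1.71 (SE 0.191) and 1.79 (SE 0.196)) and the MAP kinase phosphatase gene DUSP4 (2.68 (SE 0.183) and 1.51 (SE 0.21)). The cyclin-dependent kinase inhibitor gene CDKN2C (1.65 and 1.48), SPATA18 (1.39 and 2.70), PHLDA3 (1.26 and 2.22), the pro-apoptotic gene BBC3 (1.26 and 2.12), PTCHD4 (1.20 and 1.53), PABPN1 (1.19 and 1.28) and EGR1 (1.78 and 1.17) followed in the authors' deposited tables. The largest falls in the authors' deposited tables were of the glutathione transferase gene GSTM1 (-3.36 (SE 0.246) and -3.29 (SE 0.251)), PAGE1 (-2.71 (SE 0.112) and -6.19 (SE 0.235)) and the hyaluronan receptor gene CD44 (-2.58 (SE 0.254) and -4.54 (SE 0.32)). The nitric oxide synthase gene NOS2 (-2.29 and -2.13), the transcription factor gene SALL4 (-2.07 and -2.05), TRIM37 itself, the acetylcholine receptor gene CHRNA9 (-3.36 and -1.24), PDZRN4 (-1.47 and -1.20), the calcium release channel gene ITPR3 (-1.19 and -2.30) and LRRN2 (-1.11 and -1.68) followed in the authors' deposited tables.

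**Figure D2:**
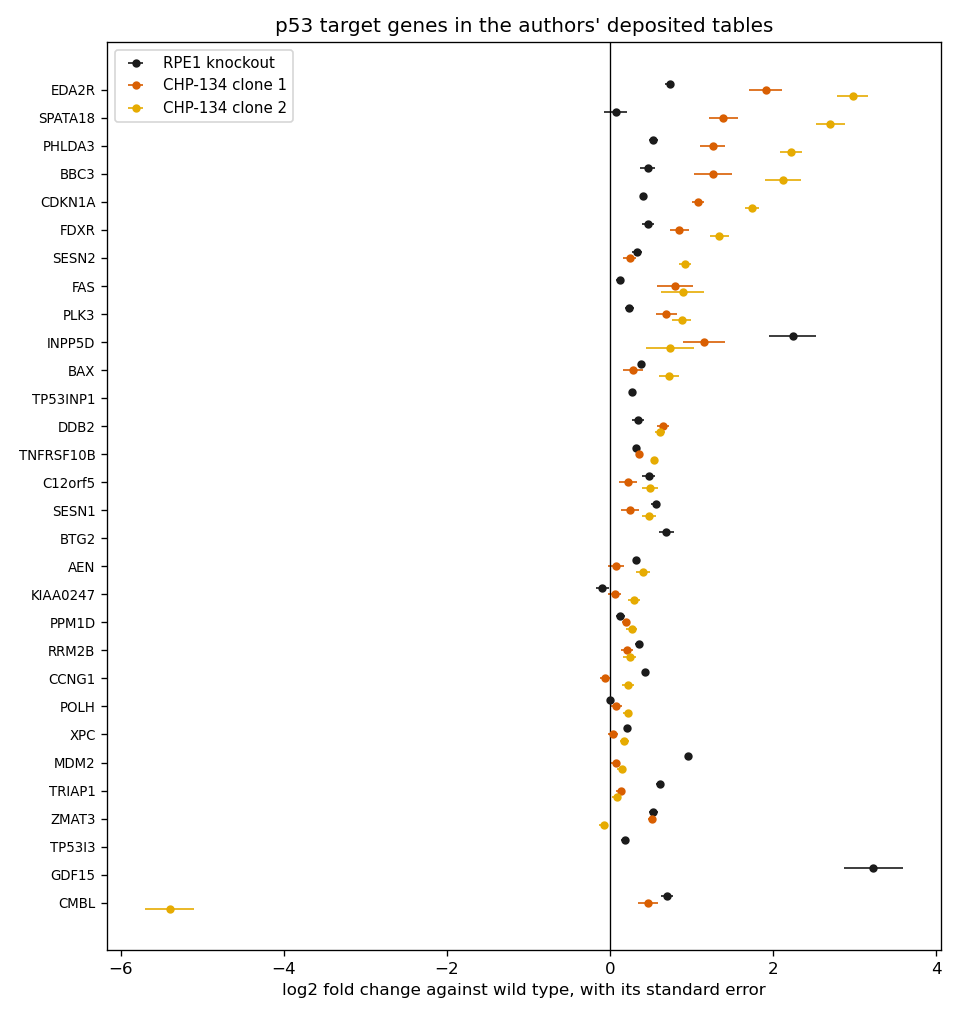
Log2 fold change against wild type (horizontal axis, with the authors' SE as bars) of each usable gene of the p53 target list (vertical axis), in the RPE1 knockout and the 2 CHP-134 mutant clones. Of the 26 genes usable in all 3 comparisons, 13 were called up in each, and CMBL in clone 2 stands apart at -5.40.

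The p53 targets went 16 up and 0 down of 26, or 20 up and 0 down adjusted over the list alone in clone 1 (median 0.32, adjusted p = 5.35e-18). In clone 2 they went 23 up and 1 down of 26 (median 0.52, adjusted p = 2.8e-13), the member that fell being CMBL. CDKN1A was at 1.08 (SE 0.0764) and 1.74 (SE 0.0862), the DNA repair gene DDB2 at 0.65 (SE 0.073) and 0.61 (SE 0.0608) and MDM2 at 0.068 (q = 0.468) and 0.14 (q = 0.0446) in the authors' deposited tables for clone 1 and clone 2. S phase and E2F genes fell, 0 up and 12 down of 33, or 0 up and 13 down adjusted over the list alone in clone 1 (adjusted p = 4.06e-05) and 3 up and 22 down of 33, or 3 up and 23 down adjusted over the list alone in clone 2 (adjusted p = 8.4e-05). The replication licensing gene CDC6 (-0.18 (SE 0.0304) and -0.33 (SE 0.0434)) and the DNA polymerase gene POLA1 (-0.20 (SE 0.0419) and -0.30 (SE 0.0379)) were called down in both clones in the authors' deposited tables. G2 and mitosis genes went 1 up and 11 down of 34, or 1 up and 18 down adjusted over the list alone in clone 1 (adjusted p = 5.77e-05). In clone 2 they went 3 up and 16 down of 34, or 3 up and 19 down adjusted over the list alone (adjusted p = 0.0053), a call that ended with a preset correlation of 0.05 (adjusted p = 0.0873) and with the GC trend removed (adjusted p = 0.0787). TOP2A was at -0.17, SE 0.0365 in clone 1 and KIF20A at -0.60, SE 0.0349 in clone 2 in the authors' deposited tables.

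Centriole and centrosome assembly genes went 0 up and 8 down of 36, or 0 up and 10 down adjusted over the list alone in clone 1 (adjusted p = 0.00322) and 2 up and 21 down of 36 in clone 2 (adjusted p = 0.0381), both downward. With a preset correlation of 0.05 neither passed (adjusted p = 0.0725 and adjusted p = 0.228), and clone 2 also missed with the GC trend removed (adjusted p = 0.203), with each chromosome's median removed (adjusted p = 0.074) and at a mean count of at least 100 (adjusted p = 0.0587). PLK4 was at -0.17 (q = 0.0155) and -0.25 (q = 0.000225) and USP28 at -0.23 (q = 0.000257) and -0.30 (q = 4.46e-06) in the authors' deposited tables for clone 1 and clone 2. CEP192 was at -0.14 (q = 0.0347) and -0.011 (q = 0.92), TP53BP1 at -0.043 (q = 0.496) and 0.12 (q = 0.0329) and PEX5 at 0.042 (q = 0.678) and 0.093 (q = 0.192) in the authors' deposited tables.

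Adrenergic neuroblastoma and neuronal genes rose in clone 1, 13 up and 1 down of 22, or 15 up and 2 down adjusted over the list alone (adjusted p = 3.45e-11). In clone 2 they went 7 up and 11 down of 23, or 8 up and 11 down adjusted over the list alone (adjusted p = 0.153, and adjusted p = 0.00872, downward, with the GC trend removed), and the test of the difference between the clones passed (adjusted p = 4.37e-07). The Status Outlier set aside 13 of 35 members above the count limit in clone 1 and 13 of 36 in clone 2, of which 8 would have passed upward and 3 downward in clone 2 if kept. With these kept the list passed in clone 1 (adjusted p = 7.99e-09), not in clone 2 (adjusted p = 0.363), and in the test of the difference (adjusted p = 9.64e-05). The secretogranin gene SCG2 (1.39 (SE 0.0613) and -0.93 (SE 0.0749)) and the noradrenergic regulator gene PHOX2A (0.44 (SE 0.0462) and -0.86 (SE 0.0485)) were called with opposite signs in the authors' deposited tables, and the oncogene MYCN was at 0.35 (q = 1.01e-06) and 0.0060 (q = 0.947). Mesenchymal neuroblastoma genes fell in clone 2, 3 up and 9 down of 20 (adjusted p = 0.00155, and adjusted p = 0.202 on ranks). In clone 1 they went 4 up and 5 down of 20, or 5 up and 5 down adjusted over the list alone (adjusted p = 0.322), with S100A6 at 0.55 (SE 0.122) and -5.42 (SE 0.301) in the authors' deposited tables. Immediate early genes rose in clone 1, 7 up and 0 down of 18, or 11 up and 0 down adjusted over the list alone (adjusted p = 0.000128), and went 8 up and 1 down of 17 in clone 2 (adjusted p = 0.0683, and adjusted p = 0.0383, upward, with each chromosome's median removed). The signalling inhibitor gene SPRY2 was at 1.05 (SE 0.16) and 1.53 (SE 0.156) in the authors' deposited tables.

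Neighbours of TRIM37 on its chromosome went 2 up and 10 down of 29 in clone 1, a downward test (adjusted p = 0.00407) that ended with a preset correlation of 0.05 (adjusted p = 0.0672) and with the GC trend removed (adjusted p = 0.168). In clone 2 they went 3 up and 13 down of 29 (adjusted p = 0.234, and adjusted p = 0.00621, downward, with each chromosome's median removed). HOX genes in clone 1 went 5 up and 0 down of 18, an upward test (adjusted p = 0.0417) that ended with a preset correlation of 0.05 (adjusted p = 0.155), on ranks (adjusted p = 0.0896), with the GC trend removed (adjusted p = 0.0861) and with Status Outlier genes kept (adjusted p = 0.057). In clone 2 HOX genes went 5 up and 2 down of 18 (adjusted p = 0.516). Unfolded protein response genes in clone 1 went 1 up and 6 down of 20, a downward test (adjusted p = 0.0378) that ended with a preset correlation of 0.05 (adjusted p = 0.155), on ranks (adjusted p = 0.0887), at a mean count of at least 100 (adjusted p = 0.0538) and with the GC trend removed (adjusted p = 0.119). In clone 2 these genes went 1 up and 7 down of 19 (adjusted p = 0.128). Cytosolic ribosomal protein genes in clone 2 went 15 up and 0 down of 34, an upward test (adjusted p = 0.00414) that ended with a preset correlation of 0.05 (adjusted p = 0.0813). In clone 1 they went 2 up and 0 down of 40 (adjusted p = 0.142, and adjusted p = 0.0176, upward, on ranks).

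Genes called in the CHP-134 clones overlapped more than independent lists would. Of 12578 genes usable in both tables, with TRIM37 left out, 622 were up in both clones against 261 for independent lists, and 605 were down in both against 282. Of the 1584 genes called in both, 1227 (77.5%) had the same sign. Simulated unchanged groups set against shared controls gave 0 genes called in both and a Pearson correlation across genes of 0.496, against 0.200 observed. Among genes at an unadjusted p under 0.05 in both tables these simulated groups had the same sign for 99.9%, against 78.9% observed, and over all genes for 66.7% against 65.3%. Over all genes the same-sign share was thus no higher than in the simulated groups. Among genes passing in both, the simulated share left no room for a higher one. The 0 genes called in both largely follows from drawing no changed genes. These 2 comparisons cannot show whether the 77.5% comes from shared controls. The simulated covariance was 0.00905 against 0.0267 observed, a difference of 0.0176. The 3 shared wild type libraries could not be split, so part of the overlap may come from them. Fold changes also followed GC content, with a Spearman correlation across genes, which are not independent, of 0.348 in clone 1 and 0.513 in clone 2.

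TRIM37 was induced in the 2 TetOn clones to ask what a raised dose does in RPE1 cells. Few genes moved and by small amounts, with falls of unfolded protein response, extracellular matrix and NF-kB genes in both clones. In clone 4, 237 of 12153 usable genes were called, 87 up and 150 down. In clone 5, 362 of 12195 were called, 97 up and 265 down. Most calls were falls, but with a change of at least 1.5-fold 6 up and 2 down were called in clone 4 and 8 up and 3 down in clone 5, TRIM37 included. An absolute log2 fold change of 1 was reached by 2 and 4 called genes, TRIM37 included. Besides TRIM37, the largest shared rises in the authors' deposited tables for clone 4 and clone 5 were of C21orf91 (1.26 (SE 0.0747) and 1.12 (SE 0.0743)), the endocytic receptor gene CUBN (0.70 (SE 0.135) and 0.98 (SE 0.16)) and the centromere protein gene CENPT (0.51 (SE 0.0628) and 0.52 (SE 0.060)). The mitochondrial cyclophilin gene PPIF (0.50 and 0.58), SLITRK5 (0.49 and 0.51), SAMD9L (0.48 and 0.53), the nuclear transport gene NUTF2 (0.52 and 0.46), the ceramide synthase gene CERS5 (0.47 and 0.38) and SLC25A36 (0.37 and 0.40) followed in the authors' deposited tables. The largest shared falls in the authors' deposited tables were of the growth factor gene BMP2 (-0.52 (SE 0.113) and -0.54 (SE 0.116)), the integrin gene ITGA2 (-0.57 (SE 0.0412) and -0.51 (SE 0.0548)) and the pentraxin gene PTX3 (-0.46 (SE 0.0364) and -0.76 (SE 0.0563)). IGFBP3 (-0.45 and -0.48), the phospholipase gene PLA2G4A (-0.53 and -0.45), KCNJ2 (-0.44 and -0.52), the ubiquitin ligase gene FBXO32 (-0.39 and -0.41), the matricellular gene THBS1 (-0.39 and -0.51), TM4SF18 (-0.38 and -0.39) and NFKBIZ (-0.40 and -0.37) followed in the authors' deposited tables.

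Unfolded protein response genes fell in both TetOn clones, 0 up and 5 down of 22, or 0 up and 6 down adjusted over the list alone in clone 4 (adjusted p = 2.72e-09) and 0 up and 6 down of 22, or 0 up and 9 down adjusted over the list alone in clone 5 (adjusted p = 3.5e-12). The endoplasmic reticulum chaperone gene HSPA5 was at -0.23 (SE 0.0263) and -0.23 (SE 0.0166) in the authors' deposited tables. Extracellular matrix genes fell, 0 up and 3 down of 18, or 1 up and 7 down adjusted over the list alone in clone 4 (adjusted p = 2.39e-05) and 1 up and 8 down of 23, or 1 up and 9 down adjusted over the list alone in clone 5 (adjusted p = 2.4e-07), THBS1 among them. The Status Outlier set aside 9 of 27 members above the count limit in clone 4 and 5 of 28 in clone 5, and both tests passed with these kept (adjusted p = 4.62e-08 and adjusted p = 1.5e-06). NF-kB and inflammatory genes fell, 0 up and 3 down of 20, or 0 up and 7 down adjusted over the list alone in clone 4 (adjusted p = 1.54e-08) and 0 up and 2 down of 19, or 0 up and 4 down adjusted over the list alone in clone 5 (adjusted p = 8.9e-06), with the cytokine gene LIF at -0.38 (SE 0.0378) and -0.34 (SE 0.0253) in the authors' deposited tables. Mesenchymal neuroblastoma genes fell, 1 up and 5 down of 25, or 1 up and 6 down adjusted over the list alone in clone 4 (adjusted p = 9.47e-05) and 1 up and 6 down of 24, or 2 up and 6 down adjusted over the list alone in clone 5 (adjusted p = 0.00168). Neither passed on ranks (adjusted p = 0.0685 and adjusted p = 0.16). The Status Outlier set aside 4 of 28 members above the count limit in clone 5, where the test passed with these kept (adjusted p = 0.00287). The transcription co-activator gene WWTR1 was at -0.22 (SE 0.0395) and -0.20 (SE 0.0344) in the authors' deposited tables.

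Other lists passed in only 1 of the TetOn clones. The tests of a difference between these clones were not run with the GC trend removed. Integrated stress and amino acid response genes rose in clone 4, 6 up and 0 down of 27, or 15 up and 0 down adjusted over the list alone (adjusted p = 1.11e-15). In clone 5 they went 0 up and 1 down of 27 (adjusted p = 0.467), and the adjusted p of the difference was 3.1e-11. ASNS was at 0.23, SE 0.0299 and the stress transcription factor gene ATF4 at 0.20, SE 0.0395 in clone 4 in the authors' deposited table. G2 and mitosis genes rose in clone 5, 7 up and 0 down of 32, or 22 up and 0 down adjusted over the list alone (adjusted p = 8.82e-16). In clone 4 they went 0 up and 0 down of 31 (adjusted p = 0.662), and the adjusted p of the difference was 1.19e-17. ANLN was at 0.15, SE 0.0291 and BUB1 at 0.15, SE 0.0381 in clone 5 in the authors' deposited table. YAP and TEAD targets fell in clone 5, 0 up and 4 down of 22, or 0 up and 6 down adjusted over the list alone (adjusted p = 3.5e-06, and adjusted p = 0.196 on ranks). In clone 4 these targets went 1 up and 1 down of 23, or 2 up and 2 down adjusted over the list alone (adjusted p = 0.662), and the adjusted p of the difference was 0.000428. The connective tissue growth factor gene CTGF was at -0.072 (SE 0.0504) and -0.38 (SE 0.025) in the authors' deposited tables for clone 4 and clone 5. Immediate early genes fell in clone 5, 0 up and 5 down of 26 (adjusted p = 0.000176). In clone 4 these genes went 2 up and 2 down of 27, or 4 up and 7 down adjusted over the list alone (adjusted p = 0.299), and the test of the difference did not pass (adjusted p = 0.0732) unless Status Outlier genes were kept (adjusted p = 0.0409).

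Some lists passed in the TetOn clones with few members called. S phase and E2F genes passed upward in clone 4, 0 up and 0 down of 35 (adjusted p = 0.0497), and clone 5, 1 up and 0 down of 35, or 1 up and 1 down adjusted over the list alone (adjusted p = 0.0156), and so did interferon-stimulated genes, 2 up and 0 down of 27 (adjusted p = 0.0152) and 1 up and 0 down of 27 (adjusted p = 0.0115). With a preset correlation of 0.05 none of these passed (adjusted p = 0.254, adjusted p = 0.15, adjusted p = 0.118 and adjusted p = 0.101). In clone 4 the S phase call also ended with each chromosome's median removed (adjusted p = 0.0645), at a mean count of at least 100 (adjusted p = 0.0527) and with Status Outlier genes kept (adjusted p = 0.0514), and the interferon call on ranks (adjusted p = 0.0828). Cholesterol and fatty acid synthesis genes passed downward in clone 4, 0 up and 0 down of 25 (adjusted p = 0.00414), but not with a preset correlation of 0.05 (adjusted p = 0.0615). The Status Outlier set aside 7 of 32 members there, and the test passed with these kept (adjusted p = 0.000863). In clone 5 these genes went 0 up and 0 down of 31 (adjusted p = 0.271). In clone 5 cytosolic ribosomal protein genes passed upward, 1 up and 0 down of 34 (adjusted p = 0.000347), and also with the 6 of 40 members kept that the Status Outlier set aside (adjusted p = 0.00226). In clone 4 they went 0 up and 0 down of 36 (adjusted p = 0.105), and passed upward on ranks (adjusted p = 0.0258), with the GC trend removed (adjusted p = 0.0193) and with Status Outlier genes kept (adjusted p = 0.0343). Retinal pigment epithelium markers passed downward in clone 5, 0 up and 2 down of 8, or 0 up and 3 down adjusted over the list alone (adjusted p = 0.0371), but not with a preset correlation of 0.05 (adjusted p = 0.0873) or on ranks (adjusted p = 0.883).

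Centriole and centrosome assembly genes went 0 up and 0 down of 37 in TetOn clone 4 (adjusted p = 0.681). In clone 5 they went 1 up and 0 down of 37, an upward test (adjusted p = 0.00412) that ended with a preset correlation of 0.05 (adjusted p = 0.0844). The p53 targets went 0 up and 0 down of 26 in clone 4 (adjusted p = 0.152, and adjusted p = 0.0296, downward, on ranks) and 1 up and 1 down of 28 in clone 5 (adjusted p = 0.41). CDKN1A was at -0.14, SE 0.0319, q = 0.00108 in clone 5 in the authors' deposited table, and carried the Status Outlier in clone 4. In the authors' deposited tables PLK4 (0.026 (q = 0.949) and 0.018 (q = 0.968)), CEP192 (-0.00013 (q = 1) and 0.048 (q = 0.874)), TP53BP1 (-0.091 (q = 0.646) and -0.0065 (q = 0.989)), USP28 (-0.068 (q = 0.802) and -0.0088 (q = 0.988)), MDM2 (-0.031 (q = 0.934) and -0.033 (q = 0.915)) and PEX5 (-0.071 (q = 0.792) and 0.12 (q = 0.545)) were not called in either clone. Of 107 genes called in both clones, with TRIM37 left out, 105 (98.1%) had the same sign. There were 28 up in both against 0.653 for independent lists, and 77 were down in both against 3.01. No doxycycline-treated cells without the TRIM37 construct were analysed here, so effects of TRIM37 and of doxycycline cannot be told apart.

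**Figure D3:**
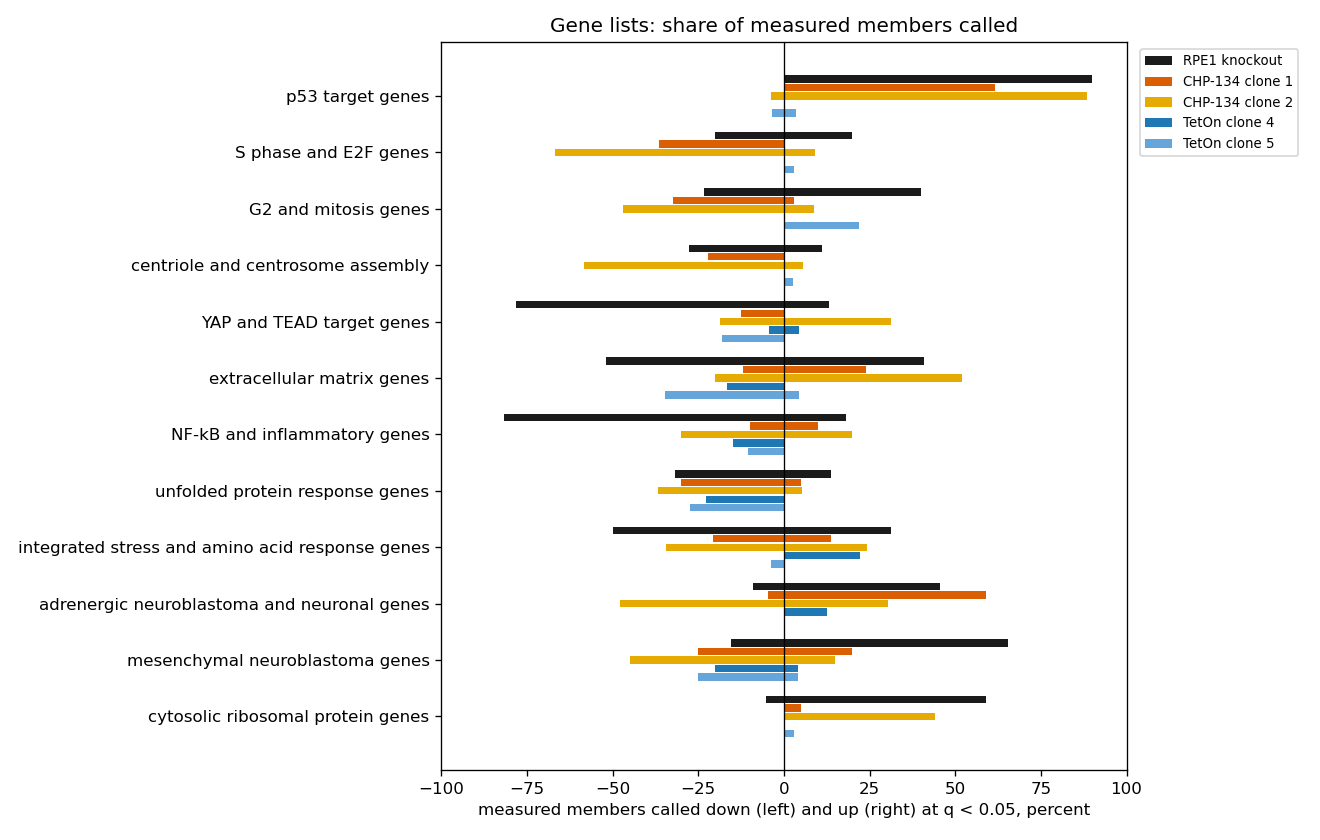
Share of the measured members of 12 gene lists (vertical axis) called down (left) and up (right) at a q under 0.05, in percent (horizontal axis), with 1 bar per comparison. Bars of the p53 targets reach to the right in the RPE1 knockout (27 of 30), CHP-134 clone 1 (16 of 26) and clone 2 (23 of 26), and that of YAP and TEAD targets to the left in the knockout (18 of 23).

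The knockout and the CHP-134 clones were set side by side to ask which changes go with lower TRIM37 in both lines. Among p53 targets, CDKN1A, BBC3, FAS, SESN2, RRM2B, DDB2, PLK3, TNFRSF10B, PHLDA3, FDXR, PPM1D, EDA2R and INPP5D were called up in all 3 comparisons, 13 of the 26 usable in each. Of 1160 genes called in the knockout and clone 1, 639 (55.1%) had the same sign. There were 308 up in both against 235 for independent lists and 331 down in both against 284. Of 2873 called in the knockout and clone 2, 1570 (54.6%) had the same sign. There were 745 up in both against 595 and 825 down in both against 749. With a change of at least 1.5-fold in both tables the same sign was shared by 47 of 91 genes (51.6%) for clone 1 and by 101 of 224 (45.1%), a minority, for clone 2. Spearman's rho across genes was 0.0438 and 0.041.

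The knockout and the TetOn clones hold opposite TRIM37 doses in RPE1 cells. Of 193 genes called in the knockout and TetOn clone 4, 80 (41.5%) had the same sign, and of 278 called in the knockout and clone 5, 141 (50.7%). Genes up in the knockout and down on induction numbered 75 and 103, against 39.3 and 66.1 for independent lists. Genes down in the knockout and up on induction numbered 38 and 34, against 22.7 and 25.6. Genes down in both numbered 54 and 112, against 40.4 and 68.3. Genes up in both numbered 26 and 29, against 22 and 24.8. Spearman's rho across genes was -0.0261 and -0.0495. NF-kB and extracellular matrix genes passed downward in the knockout and both TetOn clones. In the knockout and clone 5 alike, YAP and TEAD targets passed downward and cytosolic ribosomal protein genes upward. Passing upward in the knockout and downward on induction were mesenchymal neuroblastoma genes, in both clones, and immediate early genes, in clone 5. Integrated stress and amino acid response genes passed downward in the knockout and upward in clone 4. Some of these calls ended under other settings, as given above.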

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

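The tests of list differences between comparisons, with and without Status Outlier genes, of runs of neighbouring genes, of the GC trend and other comparisons on chromosome 12, of lists with the Status Outlier and of Status Outlier sharing between clones were chosen only after the results were seen.

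The CHP-134 clones differed from each other at many genes. The Wald test of the difference passed for 2580 genes, 1169 higher and 1411 lower in clone 2, and 357 genes were called in both clones with opposite signs. Fold changes followed GC content more closely in clone 2 (Spearman correlation across genes 0.513) than in clone 1 (0.348). No test of a difference, by gene or by list, was run with that trend removed, so part of the differences may follow it. Among the named genes, called in both clones or not, the authors' deposited tables put clone 2 above clone 1 for EDA2R by 1.07, SPATA18 by 1.31, PHLDA3 by 0.96, BBC3 by 0.86, CHRNA9 by 2.12, CDKN1A by 0.66 and TP53BP1 by 0.16 on the log2 scale. The difference, clone 2 minus clone 1, was -1.17 for DUSP4, -0.61 for EGR1, -3.48 for PAGE1, -1.96 for CD44, -1.11 for ITPR3 and -0.34 for MYCN in the authors' deposited tables. Among members of lists named above it was -5.97 for S100A6, -5.87 for CMBL, -2.32 for SCG2 and -1.29 for PHOX2A in the authors' deposited tables. By list, adrenergic neuroblastoma and neuronal genes (adjusted p = 4.37e-07) and mesenchymal neuroblastoma genes (adjusted p = 0.0206) changed lower in clone 2 than in clone 1, relative to wild type. The median log2 fold changes of the mesenchymal genes were close, at -0.10 in clone 1 and -0.13 in clone 2. Their means were -0.15 and -0.78, so large falls of some members weigh on that difference.

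Between the TetOn clones 26 genes differed, 7 higher and 19 lower in clone 5. Fold changes followed GC content in opposite ways, with a Spearman correlation across genes of 0.108 in clone 4 and -0.147 in clone 5. With transcript length it was -0.130 and 0.126. No difference between these clones was tested with such trends removed, so part of the differences below may follow them. TRIM37 itself differed by -0.55 and PTX3 by -0.30, clone 5 minus clone 4, in the authors' deposited tables. G2 and mitosis genes (adjusted p = 1.19e-17), cholesterol and fatty acid synthesis genes (adjusted p = 0.000987), glycolysis and hypoxia genes (adjusted p = 0.0121), cytosolic ribosomal protein genes (adjusted p = 0.0392) and centriole genes (adjusted p = 0.0488) changed higher in clone 5 than in clone 4, each relative to its untreated cells. With Status Outlier genes kept, the difference of the ribosomal protein genes (adjusted p = 0.534) and of the centriole genes (adjusted p = 0.0524) did not pass, and that of immediate early genes (adjusted p = 0.0409), lower in clone 5, did. Between the CHP-134 clones that of ribosomal protein genes (adjusted p = 0.028), higher in clone 2, passed then as well. Integrated stress and amino acid response genes (adjusted p = 3.1e-11) and YAP and TEAD targets (adjusted p = 0.000428) changed lower in clone 5.

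The knockout and the CHP-134 clones also differed in the changes of lists, each taken against the wild type of its own line, and levels of the 2 lines were not compared. Chromosome medians were not removed in these tests, so the rise of chromosome 12 genes in the knockout may enter them. The fold changes of YAP and TEAD targets were lower in the knockout than in clone 1 (adjusted p = 0.000473) and clone 2 (adjusted p = 0.000133), and so were those of extracellular matrix genes (adjusted p = 1.92e-06 and 0.00287). These tests covered only members usable in both tables, 14 and 14 YAP and TEAD targets and 16 and 15 matrix genes. ANKRD1, CRIM1 and COL8A1, which fell in the knockout, lay below the count limit in the CHP-134 clones. The downward matrix call in the knockout did not pass on ranks, and no difference was tested on ranks. Those of ribosome biogenesis and MYC target genes were higher in the knockout than in clone 1 (adjusted p = 0.00962) and clone 2 (adjusted p = 0.0300). Against clone 2, and without passing against clone 1, the fold changes of mesenchymal neuroblastoma genes (adjusted p = 0.000176), nuclear oxidative phosphorylation genes (adjusted p = 0.0121), S phase genes (adjusted p = 0.0206) and G2 and mitosis genes (adjusted p = 0.0265) were higher in the knockout. Against clone 1 these ran the same way (adjusted p = 0.417, 0.211, 0.196 and 0.0565). The clones were not shown to differ from each other for the last 3 (adjusted p = 0.167, 0.329 and 0.676).

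Chromosome 12 genes were higher in the RPE1 knockout, and a GC content trend is argued against, as their median log2 fold change with that trend removed was 0.51. A general effect of lower TRIM37 on this chromosome is argued against within the limits of another cell line, as the higher of the medians in the CHP-134 clones, over the chromosome 12 genes with known GC content that met the count limit in the knockout too, was -0.0305. A candidate explanation is an extra copy of the chromosome in the knockout cells, as 100% of its 29 runs of 20 neighbouring genes had a median above 0.25, from 0.35 to 0.67, against 0 of 490 runs elsewhere. A change from 2 to 3 copies would give 0.58 if expression followed copy number, and no DNA was analysed here. Whether such a copy came with clone isolation or with loss of TRIM37 was not tested.

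The rise of p53 targets in the knockout and both CHP-134 clones stayed past the threshold with the GC trend removed (largest adjusted p of the 3 comparisons 3.67e-06) and with each chromosome's median removed (largest adjusted p 1.39e-06). This argues against the GC trend, and against altered dosage of the whole chromosomes that carry the targets, as the whole cause. Removing medians cannot show whether a gained or lost chromosome raised targets on other chromosomes, so that stays open. An unusual library among the CHP-134 wild type libraries cannot be told apart from an effect in the clones, since no value per library was analysed here. The Status Outlier on 3 of 29 members in either table was not shown to be more frequent than on other genes (adjusted p = 0.659 and 0.687), which neither supports nor excludes it. The knockout has its own wild type libraries, so that explanation could not cover its 27 called members. A shared effect of lower TRIM37 on p53 targets stays a hypothesis, as does selection of the clones.

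Cholesterol and fatty acid synthesis genes carried the Status Outlier in 25 of 32 cases in both CHP-134 tables (Fisher's exact test, two-sided, adjusted p = 5.72e-25 and 2.67e-24), so the authors set their q to 1. Their fold changes were below 0 for 19 of 25 in clone 1 and 19 of 25 in clone 2 (medians -0.119 and -0.346). If kept, 0 would pass in clone 1, and 1 upward and 9 downward in clone 2, against 373 upward and 101 downward of all genes with that Status in clone 2. Counts near the floor are argued against, as the median mean count of these genes in clone 1 was 3820. A candidate explanation is an unusual library among the shared wild type libraries, as 93.6% of the 671 clone 1 genes with that Status had it in clone 2 as well, 628 against 37 if independent. The TetOn clones, with separate controls, shared 90 of 295 (30.5%), against 5.29 if independent, so sharing beyond chance does not need shared controls. The same list carried the Status in 7 of 32 cases in TetOn clone 4 (adjusted p = 0.000152), extracellular matrix genes carried it more often than other genes in the knockout and both TetOn clones (adjusted p = 0.000119, 2.29e-07 and 0.00169), ribosomal protein and mesenchymal genes in TetOn clone 5 (adjusted p = 0.00108 and 0.0183), and adrenergic genes in both CHP-134 clones (adjusted p = 2.29e-07 and 6.39e-07). An unusual CHP-134 library could not explain those in RPE1 cells, and a list that varies between cultures stays open as well. No biological explanation was tested.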

How the results depend on the processing

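Keeping Status Outlier genes, removing the GC trend or chromosome medians, and leaving out chromosome 12 or a chromosome 3 segment were chosen only after the data were seen. No paired analysis was possible because the files hold no values per library. For the same reason the tests without each replicate, other splits of the samples, other scalings and pseudocounts, summed wild type libraries and an estimated correlation were not run. TRIM37 passed in all 5 comparisons under every setting tried. Its sign set the direction of each comparison, so that direction was not tested. At a threshold of 0.01, 1450 genes were called in CHP-134 clone 1, 141 in TetOn clone 4 and 240 in TetOn clone 5. With a change of at least 1.5-fold, 1646 were called in the knockout, 474 and 1508 in CHP-134 clones 1 and 2, and 8 and 11 in TetOn clones 4 and 5. The share up rose with this to 67.7 and 58.2% in the CHP-134 clones and 75 and 72.7% in the TetOn clones, from 51.4, 47.7, 36.7 and 26.8%. At an absolute log2 fold change of at least 1 the numbers called were 780, 142, 520, 2 and 4, with 47.9 and 52.3% up in CHP-134 clones 1 and 2. With the rescaled null, 1262 were called in the knockout, 243 in CHP-134 clone 1 (63.8% up, against 51.4% as deposited) and 256 in clone 2 (38.3% up, against 47.7%). The counts at the stricter threshold and at a minimum fold change fall by construction, as each setting asks more of a gene. Those with the rescaled null do not. They fell because the central spread of the statistics was wider than the assumed null. Under the other settings counts stayed within 1.5 times, the GC trend removed leaving 3295 of the 5898 called in clone 2.

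The same-sign share of the CHP-134 clones was 75.3% at a threshold of 0.01, 79.6% at a mean count of at least 100 and 66.2% with at least 1.5-fold. For the TetOn clones it was 100% at 0.01 and 100% with at least 1.5-fold (2 of 2 genes). With at least 1.5-fold it was 100% (4 of 4) and 60% (3 of 5) for the knockout with TetOn clones 4 and 5, and 51.6% and 45.1% with CHP-134 clones 1 and 2. For clone 2 it was 56.6% at a mean count of at least 100 and 56.7% without chromosome 12. Genes that differed numbered 1104 for the CHP-134 clones with at least 1.5-fold, and for the TetOn clones 17 at 0.01 and 5 with at least 1.5-fold. Of 45 list tests past the threshold, 29 passed with a preset correlation of 0.05, 33 on ranks, 41 at a mean count of at least 100, 40 with the GC trend removed, 43 with chromosome medians removed and 43 with Status Outlier genes kept, and 0 turned direction. Newly passing were 9 on ranks, 1 at that mean count, 6 with the GC trend removed, 3 with chromosome medians removed and 1 with Status Outlier genes kept. At the mean count of at least 100 HOX genes in the knockout had too few members left to be tested. Of 459 calls of named genes, TRIM37 left out, 218 did not pass with the rescaled null and 36 with the GC trend removed, which added 7. Those that did not pass numbered 278 with at least 1.5-fold, 346 at an absolute log2 fold change of at least 1, and 37 at 0.01. Among named genes EED in clone 2 turned, from -0.14 in the authors' deposited table to 0.077 with the GC trend removed. The cause was not tested where none is given.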

Other observations

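All tests here, and all genes named here except DUSP4 in the CHP-134 clones, MITF, CENPT and NUTF2, were chosen only after their values were seen.

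Some genes moved far in opposite directions in the 2 CHP-134 clones. In the authors' deposited tables for clone 1 and clone 2, GTSF1 was at -3.74 (SE 0.259) and 2.81 (SE 0.107), the calcium-binding protein gene RCN1 at -3.36 (SE 0.161) and 2.41 (SE 0.104) and the actin-binding protein gene CALD1 at -2.57 (SE 0.211) and 2.52 (SE 0.112). Others were far lower in clone 2 and not in clone 1, with the retinaldehyde dehydrogenase gene ALDH1A1 at 0.22 (SE 0.167) and -5.24 (SE 0.289), ZNF83 at 0.46 (SE 0.116) and -5.57 (SE 0.298) and GAGE1 at 0.035 (SE 0.0758) and -8.56 (SE 0.249) in the authors' deposited tables.

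Across the knockout and both CHP-134 clones, 165 of 11053 genes were called up in all 3 against 124 if the knockout were independent of the clones, and 168 were called down in all 3 against 153. DUSP4 was at 1.55 in the knockout and 2.68 and 1.51 in the clones in the authors' deposited tables. With doxycycline it was at -0.19 and -0.19 in the TetOn clones in the authors' deposited tables. It was the only gene of these sets called in the opposite direction in both TetOn clones. Of 11777 genes usable in both TetOn clones, 77 were down in both. Finding 1 such gene among the 165 is thus near what independent lists would give. MITF, a melanocyte and pigment epithelium transcription factor gene, was at -0.77, -0.54 and -0.52, and TFAP2A at -0.70, -1.27 and -0.97 in the authors' deposited tables for the knockout, clone 1 and clone 2.

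In CHP-134 clone 2 the 118 measured genes of chromosome 3 from PLCH1 to the end had a median log2 fold change of -0.57, 107 called down and 1 up, against -0.053 for the 478 genes before it. A run of 20 genes on chromosome 13 from PIBF1 to TGDS was at 0.59 in clone 1 and 0.50 in clone 2.

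Neighbouring genes moved in opposite directions in the TetOn clones. CENPT (0.51 and 0.52) and NUTF2 (0.52 and 0.46) rose and their neighbour THAP11 (-0.23 and -0.57) fell in clones 4 and 5 in the authors' deposited tables. In clone 4 PCNXL3 was at 0.62 beside SIPA1 at -0.61, and in clone 5 PTPRF was at 0.92 beside HYI at -0.36, in the authors' deposited tables. FNDC3A was at 1.41 in clone 5 and 0.12 in clone 4 in the authors' deposited tables.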
